A study of Mus musculus with 29 samples.

How the data were processed

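The study measured polyadenylated RNA in MC38 cells, a mouse colorectal cancer line, after transduction with Cas9 and a single guide RNA. A guide targeted BRD9, LIMCH1 or RAD51D, or had no target in the control, which the labels call wildtype and which is named WT here. There were 18 WT libraries, 4 of the BRD9 knockout, 4 of the LIMCH1 knockout and 3 of the RAD51D knockout, 29 in all. Per the labels, cells grew in DMEM, RNA was taken with TRIzol, and paired-end reads came from a DNBSEQ-T7 instrument. Every library carries the same batch label. Nothing in the labels says that replicates came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

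The authors deposited 1 table of raw counts per gene, not normalized. The submitters' processing notes name HISAT2, featureCounts and the mouse assembly GRCm39, and their versions, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The table held 51826 entries named by symbol, of which 91 symbols stood on more than 1 entry (183 entries) and 11 had been turned into dates. Only 31.3% of the counts between 1 and 10 were odd, so a fragment did not always give 1 count. Symbols of 92.0% of the entries matched the GRCm38 annotation (GENCODE M21 and the RefSeq table of GRCm38.p6), which was used only for names and for the order of neighbouring genes. No coordinates are given, because the builds differ. Genes with near-identical copies, such as the H2, Gbp and Ifit families and ribosomal proteins with pseudogenes, and genes that overlap another gene or an antisense transcript, have uncertain values because the counting could split or merge their reads.

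Total counts per library ranged from 30477422 to 52423481 in WT, from 31429032 to 34644425 in the BRD9 knockout, from 29218349 to 41876178 in the LIMCH1 knockout and from 32072803 to 40508808 in the RAD51D knockout. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 5.14, between WT 4 and WT 5. Every library was kept as a separate sample in the main fit, which does not make the libraries independent. Of BRD9 and of LIMCH1 knockout the 4 libraries formed 2 pairs with like profiles along the chromosomes. The p-values of the main fit take the libraries of a pair as independent.

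Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr over the groups, which left 16240, and libraries were scaled by TMM. A quasi-likelihood model of all 29 libraries with 1 term per group gave each contrast, with Benjamini-Hochberg adjustment within a contrast, a threshold of 0.05 on the adjusted p and two-sided tests throughout. Levels are CPM after TMM scaling as mean ± SD, and log2 fold changes are given with a standard error (SE). The SE was worked back from the quasi-likelihood test, as the absolute log2 fold change divided by the square root of the F statistic. Log2 CPM used a prior count of 2. Camera compared each of 24 gene lists with the other genes at a preset correlation of 0.01, adjusted over the lists and the 3 contrasts against WT, and was repeated with the correlation estimated from the data. A list needed 5 tested members. Counts within a list are given over all genes tested and adjusted over the list alone. The lists cover the JAK-STAT-IRF1 axis, checkpoint ligands, interferon-stimulated genes, interferon-gamma GTPases and chemokines, MHC class I, NF-kB and cytokines, cGAS-STING, other PD-L1 regulators, BAF complexes, homologous recombination, p53 targets, actomyosin, YAP and SRF targets, cell cycle, epithelial genes, mesenchymal and matrix genes, hypoxia and glycolysis, integrated stress with the unfolded protein response, cholesterol synthesis, heat shock, mitochondrially encoded genes, cytosolic ribosomal proteins, leukocyte markers, and fibroblast with endothelial markers. Of their names, 7 were found by a synonym and 3 were not in the table. A list's level in a library is the mean of its members' log2 differences from the WT mean.

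The groups, tests, lists, named-gene rule and first set of alternatives were fixed before the data were examined. The rule names, for each knockout against WT, the targeted gene, Cd274, Jak1, Stat1 and Irf1. It adds the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM in either group and every knockout library beyond the WT 90th or 10th percentile, leaving out names of Gm with digits, names ending in Rik, Ensembl and LOC identifiers and pseudogene names with -ps and digits. From each list described, it takes up to 4 members with the smallest adjusted p. Between knockouts it takes 5 genes each way with no overlap between the libraries of the groups.

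Alternatives were DESeq2 1.42.0 with its Wald test, DESeq2 size factors or total counts in place of TMM, no low-count filter, a stricter filter (CPM of 1 in 4 libraries and 100 counts), robust dispersion, 1 surrogate variable from sva 3.50.0, a fit of the compared groups alone, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn. Chosen after seeing the data were the sum of libraries with like profiles along the chromosomes (correlation above 0.8), an offset per gene from the 100 nearest measured genes, the mitochondrial share of counts as a covariate, the omission of WT 8, WT 13 and WT 14, and the omission of LIMCH1 3 and 4 and RAD51D 2, which have like profiles across groups. A line here means libraries of 1 group with such like profiles, and no label names lines. All 136 choices of 2 among the BRD9 and WT lines were compared with libraries of 1 line summed, also chosen after seeing the data. So was a count of the highest number of the 23 most fallen genes on any chromosome, by limma on summed lines, for LIMCH1 knockout and for each choice of 2 WT lines against the others. Fold changes against the shared WT libraries were compared across knockouts beside 100 simulated unchanged groups, and with WT split at random 20 times.

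The steps were tested on simulated counts for 16240 genes. For the BRD9 contrast 20.9% of the genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold were called, for LIMCH1 38.8%, 71.2% and 92.4%, and for RAD51D 16.4%, 71.6% and 92.4%. Of the unchanged genes, 3 of 16040, 5 of 16020 and 2 of 16040 were called in these contrasts. Libraries were drawn independently around 1 WT mean per gene, without lines. The changes counted here were given only to genes of at least 1 CPM. Among the real libraries, groups of WT libraries alone called up to 1477 and 2064 genes at the LIMCH1 and RAD51D group sizes. The simulated rates leave out this structure and may not hold for these samples. Intervals for low counts are exact Clopper-Pearson intervals at 95% confidence, which cover counting error in pooled counts only and leave out spread between libraries. Those for Limch1 were repeated with 2 counts taken as 1 fragment. Genes of the simulated unchanged groups were ranked by limma's moderated statistic to count shared top genes.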

Results

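RNA was sequenced from MC38 cells, a mouse colorectal cancer line, that carried a guide RNA against BRD9 (n = 4), LIMCH1 (n = 4) or RAD51D (n = 3), and from non-targeting control cells (WT, n = 18). BRD9 is a bromodomain subunit of a chromatin-remodelling BAF complex, LIMCH1 an activator of non-muscle myosin II, and RAD51D a RAD51 paralog that acts in homologous recombination. Total counts per library lay between 29218349 and 52423481, and 16240 genes were tested. Mitochondrially encoded genes took 2.77 ± 2.18% of the counts in WT (SD, n = 18), 5.03 ± 1.16% in BRD9 knockout (n = 4), 1.78 ± 0.265% in LIMCH1 knockout (n = 4) and 1.72 ± 0.0861% in RAD51D knockout (n = 3). WT 8 held the highest share, 11.0%.

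Brd9 was at 32.5 ± 17.7 CPM in BRD9 knockout against 59.97 ± 9.45 CPM in WT, a log2 fold change of -0.88 (SE 0.19, adjusted p = 0.00144 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 4 libraries split: replicates 3 and 4 held 15.7 and 18.9 CPM, while replicates 1 and 2, at 45.9 and 49.5 CPM, lay inside the WT range of 45.6 to 91.2 CPM. Rad51d was at 15.8 ± 2.56 CPM in RAD51D knockout against 26.5 ± 4.02 CPM in WT, a log2 fold change of -0.75 (SE 0.14, edgeR adjusted p = 0.0378). All 3 libraries, at up to 17.7 CPM, lay below the lowest WT library at 19.2 CPM. Without replicate 1, 2 or 3 the Rad51d fold change was -0.62, -0.84 or -0.80, with edgeR adjusted p = 0.430, 0.107 or 0.1496. Limch1 was barely detected in any group: WT held 23 counts in 7 of 18 libraries, or 0.0318 CPM pooled (95% exact interval 0.0202 to 0.0477, or 0.0172 to 0.0580 with 2 counts taken as 1 fragment). WT 14 alone held 10 of these counts, at 0.238 CPM, and the other 17 WT libraries 0.0191 CPM. LIMCH1 knockout held 12 counts, or 0.0878 CPM (0.0453 to 0.153, or 0.0322 to 0.191). BRD9 knockout held 10 Limch1 counts, or 0.0748 CPM, and RAD51D knockout 4, or 0.0380 CPM. The LIMCH1 label therefore could not be checked from its gene, and a transcript level does not read an edit of the coding sequence in any of the knockouts.

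**Figure D1:**
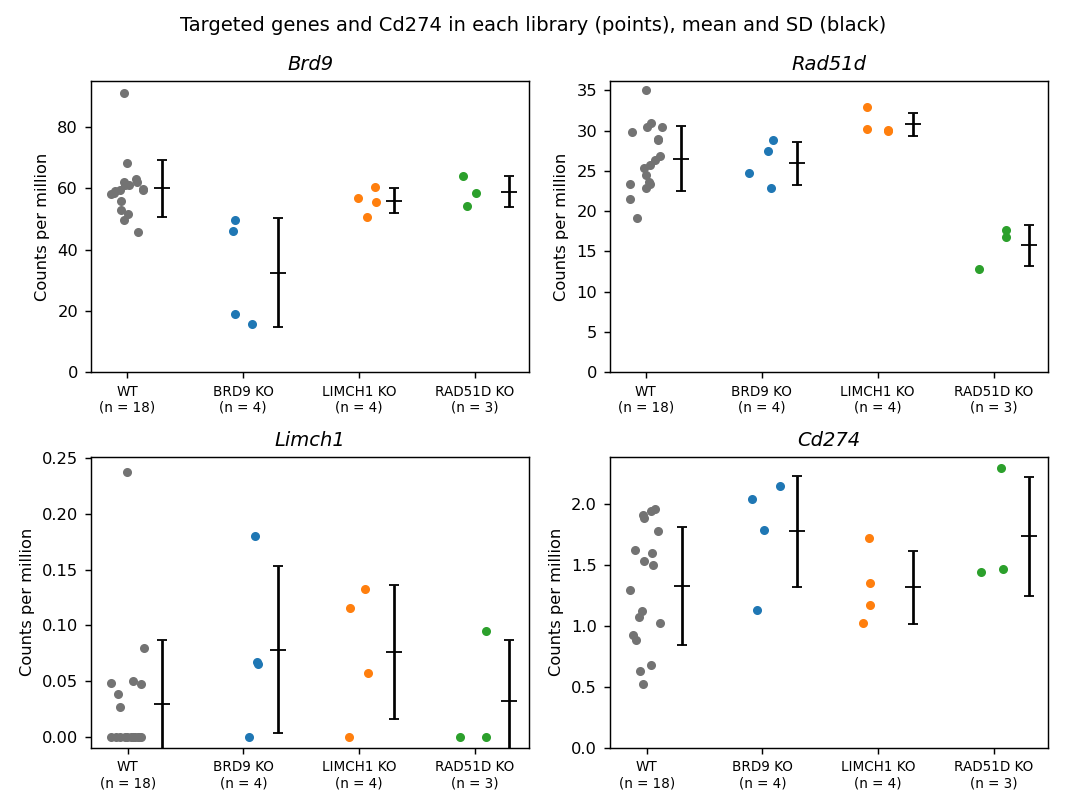
CPM (vertical axes) of Brd9, Rad51d, Limch1 and Cd274 in each library, as points, by group, with the group mean and SD in black. Brd9 fell to 15.7 and 18.9 CPM in a pair of BRD9 knockout libraries, Rad51d lay at or below 17.7 CPM in RAD51D knockout, and Cd274 overlapped between all groups.

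The design asks whether loss of each gene alters PD-L1 transcription and the JAK1-STAT1-IRF1 axis, which carries the interferon-gamma signal to the PD-L1 gene. Cd274, which encodes PD-L1, was a low transcript at 1.33 ± 0.484 CPM in WT (n = 18), and no knockout moved it past the test. Its level was 1.78 ± 0.458 CPM in BRD9 knockout (log2 fold change 0.42, SE 0.29, edgeR adjusted p = 0.278) and 1.32 ± 0.302 CPM in LIMCH1 knockout (-0.01, SE 0.29, edgeR adjusted p = 0.989). In RAD51D knockout it was 1.74 ± 0.488 CPM (0.39, SE 0.32, edgeR adjusted p = 0.621). Jak1, the receptor-bound kinase, had log2 fold changes of 0.20 (SE 0.12), -0.16 (SE 0.13) and -0.15 (SE 0.14) in BRD9, LIMCH1 and RAD51D knockout from a WT level of 175 ± 27.2 CPM, with edgeR adjusted p = 0.213, 0.506 and 0.677. Stat1, the transcription factor that Jak1 activates, was at 4.54 ± 1.14 CPM in WT, with log2 fold changes of -0.35 (SE 0.26), -0.00 (SE 0.26) and 0.60 (SE 0.27) and edgeR adjusted p = 0.327, 0.995 and 0.415. The BRD9 libraries split in both genes. Jak1 was at 163 and 153 CPM in replicates 1 and 2 and at 251 and 239 CPM in replicates 3 and 4. Stat1 was at 1.55 and 2.28 CPM in replicates 1 and 2 and at 4.77 and 5.64 CPM in replicates 3 and 4. Irf1, which binds the PD-L1 promoter, was at 47.1 ± 10.8 CPM in WT and at 67.1 ± 13.1 CPM in LIMCH1 knockout (0.51, SE 0.16, edgeR adjusted p = 0.114). Its log2 fold changes in BRD9 and RAD51D knockout were -0.07 (SE 0.17, edgeR adjusted p = 0.793) and -0.09 (SE 0.19, edgeR adjusted p = 0.861). A p that missed the threshold leaves changes undecided, including ones larger than these errors. For Cd274 in RAD51D knockout the 95% interval of the log2 fold change, not adjusted over genes, ran from -0.27 to 1.04. That is 0.83-fold to 2.06-fold, so a 2-fold rise was not excluded there.

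BRD9 knockout against WT asks what loss of this chromatin regulator does to the transcriptome and its immune genes. Dpt, which encodes the matrix protein dermatopontin, was at 43.3 ± 45.7 CPM against 1.31 ± 2.22 CPM in WT (log2 fold change 5.04, SE 0.75, n = 4 and 18). Sema3c, a secreted guidance cue, rose from 16.0 ± 9.89 to 151 ± 59.3 CPM (3.24, SE 0.41). S100a4, a calcium-binding protein linked to motility, fell from 77.6 ± 45.2 to 7.71 ± 1.75 CPM (-3.33, SE 0.50). Ltbp2, a latent TGF-beta binding protein of the matrix, fell from 224 ± 60.8 to 41.7 ± 25.7 CPM (-2.42, SE 0.31). The other large rises were in Lhfpl4 (5.01, SE 0.59), the basement-membrane gene Nid1 (4.81, SE 0.65), and the formin Fhod3 (3.42, SE 0.39). They also included the stathmin Stmn4 (3.34, SE 0.35), the syndecan Sdc3 (3.06, SE 0.59), AC122354.1 (2.88, SE 0.33), a clone name of a form that the rule did not leave out, Pknox2 (2.85, SE 0.55) and the protease Adamts6 (2.63, SE 0.36). The other large falls were in the kallikrein Klk10 (-3.15, SE 0.59), the cytokine receptor-like gene Crlf1 (-3.05, SE 0.77), and the nuclear receptor Rorc (-2.86, SE 0.60). They also included Sec1 (-2.71, SE 0.32), Rap1gap2 (-2.60, SE 0.40), Metrn (-2.51, SE 0.61), the chemokine Cx3cl1 (-2.49, SE 0.48) and the water channel Aqp5 (-2.43, SE 0.51). These 20 genes had adjusted p from 9.32e-07 to 0.00384 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 2159 genes rose and 2654 fell, 29.6% of those tested, and 630 and 690 of them moved at least 2-fold.

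In the immune lists of BRD9 knockout, of 18 JAK-STAT-IRF1 genes 5 rose and 0 fell (5 and 0 adjusted over the list alone). They included the interferon-gamma receptor chain Ifngr2 (50.3 ± 3.87 against 29.5 ± 7.47 CPM in WT), Jak2 (50.1 ± 8.94 against 29.03 ± 11.0 CPM), Ptpn2, a phosphatase that restrains the pathway (1.02, SE 0.24), and Ifnar1 (0.50, SE 0.13). Camera did not call that list (adjusted p = 0.0564). Of 36 interferon-stimulated genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), and camera called the list higher with adjusted p = 0.00339, and adjusted p = 0.439 with an estimated correlation. Ifit2 (53.8 ± 5.19 against 26.6 ± 7.84 CPM), Lgals3bp (1.08, SE 0.21) and the kinase Eif2ak2 (1.02, SE 0.22) rose, and Bst2, which tethers budding virus, fell (-1.06, SE 0.27). Of 16 interferon-gamma GTPases and chemokines 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0460, and adjusted p = 0.439 with an estimated correlation). In the cGAS-STING list 3 of 12 rose and 0 fell (3 and 0 adjusted over the list alone), with camera adjusted p = 0.0419, and adjusted p = 0.163 with an estimated correlation. Among them were the kinase Tbk1 (85.0 ± 2.75 against 55.6 ± 12.5 CPM) and the DNA sensor Aim2 (3.54, SE 0.78). Of 21 MHC class I genes 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.753), one being the immunoproteasome subunit Psmb10 (-0.97, SE 0.22). Of 12 checkpoint ligands 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.225), one being Cd276, which encodes B7-H3 (37.0 ± 5.52 against 17.0 ± 5.97 CPM). Of 20 NF-kB and cytokine genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.524), among them the subunit Nfkb2 (-0.73, SE 0.17). Of 21 PD-L1 regulators outside JAK-STAT 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0742). The ubiquitin ligase Stub1 rose (0.58, SE 0.11), and Cmtm4, which protects PD-L1 from degradation, fell (-0.98, SE 0.17). Every member named here as risen or fallen passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, with adjusted p from 0.000160 to 0.00821.

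Of 42 cytosolic ribosomal protein genes in BRD9 knockout 36 fell and 1 rose (37 and 1 adjusted over the list alone), with a median log2 fold change of -0.67 and camera adjusted p = 1.21e-14, or adjusted p = 0.142 with an estimated correlation. Rpl3 went from 1163 ± 300 CPM in WT to 561 ± 26.8 CPM, and Rps23 from 594 ± 178 to 218 ± 67.8 CPM, values that processed pseudogenes make uncertain. The list took 2.72 ± 0.229% of the counts (SD, n = 4) against 4.19 ± 0.783% in WT, in the same libraries in which the mitochondrial share was 5.03%. WT 8, with the highest mitochondrial share, held 2.56%, within the range of the BRD9 libraries. In the mean log2 difference of the list all 4 (-0.71 ± 0.0834) lay below the lowest WT library, WT 8 at -0.59. Of 24 cholesterol synthesis genes 10 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 0.000672, and adjusted p = 0.411 with an estimated correlation). They included Msmo1 (37.3 ± 3.56 against 76.9 ± 18.9 CPM) and Fdps (-1.60, SE 0.36). Of 30 integrated stress and unfolded protein genes 9 fell and 2 rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.483 with an estimated correlation). Among the falls were the serine synthesis enzymes Phgdh (248 ± 31.4 against 671 ± 213 CPM) and Psat1 (-0.77, SE 0.13). Of 31 mesenchymal and matrix genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.0128, and adjusted p = 0.206 with an estimated correlation). Among them were Fn1, which encodes fibronectin (929 ± 626 against 208 ± 129 CPM), and the transcription factor Snai2 (95.7 ± 47.9 against 29.2 ± 16.7 CPM). Of 28 genes of BAF complexes 10 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.00399, and adjusted p = 0.218 with an estimated correlation). Both partners specific to the BRD9-containing complex rose, Gltscr1l (64.7 ± 4.64 against 33.1 ± 5.21 CPM) and Gltscr1 (0.70, SE 0.14), while Actl6a fell (-0.77, SE 0.13). Of 13 mitochondrially encoded genes 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0140, and adjusted p = 0.483 with an estimated correlation).

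Camera called none of the other BRD9 lists, with adjusted p from 0.0552 to 0.753, though single members moved. Of 40 cell cycle genes 13 fell and 1 rose, and the same numbers held adjusted over the list alone; the licensing factor Cdt1 went from 159 ± 34.9 to 71.6 ± 13.7 CPM. Of 31 homologous recombination genes 9 fell and 3 rose (10 and 3 adjusted over the list alone), and of 34 p53 targets 4 and 2 (2 and 1). The counts were, of 35 actomyosin genes, 6 and 8 (6 and 8), and of 22 YAP and SRF targets 1 and 4 (0 and 2). Actn1 (701 ± 115 against 454 ± 65.8 CPM) and Ankrd1 (360 ± 208 against 102 ± 39.7 CPM), an actin crosslinker and a YAP target, rose. Of 30 hypoxia and glycolysis genes 3 fell and 5 rose (3 and 5), of 16 heat shock genes 1 and 2 (1 and 1), and of 8 epithelial genes 0 and 1 (0 and 0). They were, of 7 leukocyte markers, 0 and 1 (0 and 1), and of 11 fibroblast and endothelial markers 1 and 1 (1 and 1). The fibroblast list had a median of -0.25 and the YAP and SRF list one of -0.06, against a higher direction in camera for both. The count of calls dropped to 746 when libraries with like chromosome profiles were summed and to 1610 with the mitochondrial share as a covariate. Under the first of these Ifngr2, Ptpn2, Ifnar1, Jak2, Eif2ak2, Bst2, Psmb10, Nfkb2, Tbk1, Fdps, Crlf1, Rorc and Metrn were no longer called, and under the second Ptpn2, Jak2, Eif2ak2, Bst2, Psmb10, Nfkb2, Tbk1, Aim2, Crlf1 and Metrn. Camera's call of the interferon-gamma list ended without WT 8, 13 and 14 (adjusted p = 0.0810), with the compared groups alone (0.119), the neighbour offset (0.0532) or DESeq2 size factors (0.0521). That of cGAS-STING ended with a surrogate variable (0.0716) or the mitochondrial share (0.147), and that of integrated stress without the same 3 WT libraries (0.0567), with the offset (0.0737) or the mitochondrial share (0.129). The mitochondrial list turned lower with the mitochondrial share (0.363), a covariate that holds the list's own genes, so losing this call follows by construction.

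**Figure D2:**
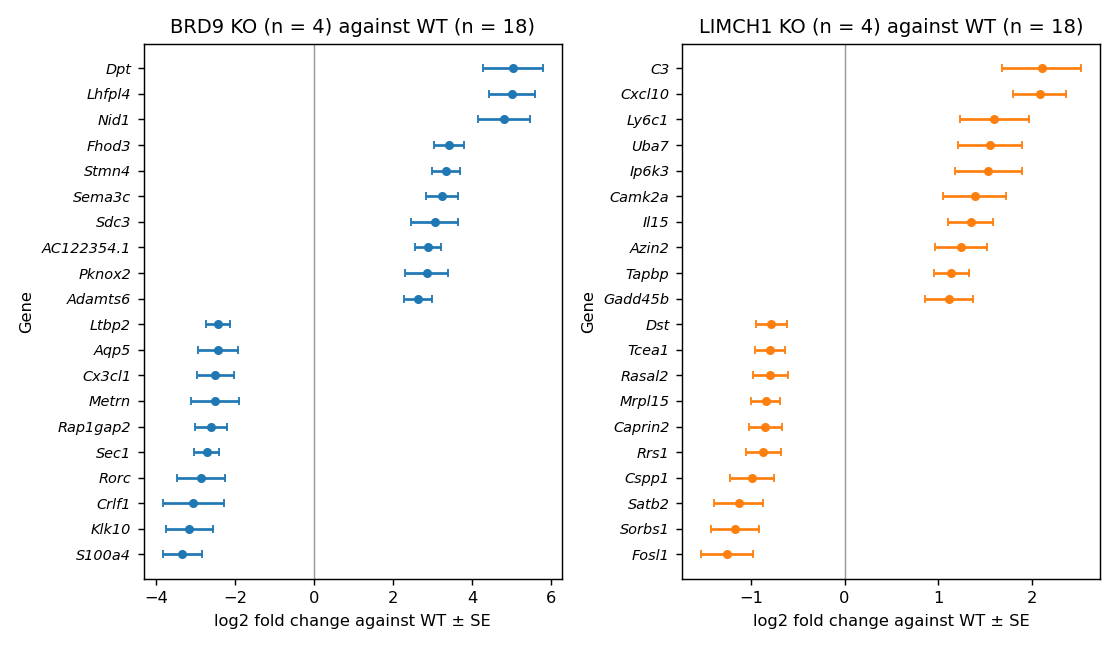
Log2 fold change against WT (horizontal axes) with SE bars for the 10 largest rises and 10 largest falls that passed the naming rule, in BRD9 knockout and LIMCH1 knockout. BRD9 changes reached 5.04 for Dpt and -3.33 for S100a4, and LIMCH1 changes reached 2.10 for C3 and -1.25 for Fosl1.

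LIMCH1 knockout against WT asks the same of a myosin regulator that these cells barely transcribe. Cxcl10, a chemokine that draws T cells, was at 12.8 ± 7.29 CPM (n = 4) against 3.02 ± 1.12 CPM in WT (n = 18; log2 fold change 2.08, SE 0.28). Tapbp, which loads peptides on MHC class I, was at 136 ± 33.2 against 61.8 ± 16.0 CPM (1.14, SE 0.19). The cytokine Il15 was at 9.85 ± 0.765 against 3.87 ± 1.33 CPM (1.34, SE 0.24) and the complement gene C3 at 7.13 ± 4.44 against 1.65 ± 1.03 CPM (2.10, SE 0.42). Fosl1, an AP-1 subunit, fell from 344 ± 137 to 144 ± 20.7 CPM (-1.25, SE 0.28). The other rises taken by the rule were in Ly6c1 (1.60, SE 0.37), the ISG15-activating enzyme Uba7 (1.55, SE 0.34), Ip6k3 (1.53, SE 0.36), Camk2a (1.39, SE 0.33), Azin2 (1.24, SE 0.28) and Gadd45b (1.11, SE 0.26). The other falls were in Sorbs1 (-1.17, SE 0.26), the chromatin organiser Satb2 (-1.13, SE 0.26), Cspp1 (-0.99, SE 0.23), Rrs1 (-0.87, SE 0.19), Caprin2 (-0.84, SE 0.18), Mrpl15 (-0.84, SE 0.15), Rasal2 (-0.79, SE 0.19), Tcea1 (-0.79, SE 0.16) and the cytolinker Dst (-0.78, SE 0.16). These 20 genes had adjusted p from 0.000452 to 0.0492 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all 65 genes rose and 24 fell, of which 53 and 5 moved at least 2-fold. The share of rises, 73.0%, was 72.3% with DESeq2 size factors, but by DESeq2's Wald test 41.9% of 351 calls were rises, so the balance of rises and falls turned with the test. Of the fallen genes 12 of the 23 placed on the reference lay on chromosome 1, against 847 of the 14183 placed genes tested. Fisher's exact p was 1.40e-09, but the chromosome was chosen after the genes were seen and neighbouring genes are not independent. With lines summed, 6 of the 23 most fallen genes lay on chromosome 1, and 41 of 106 groupings of lines, the real one included, placed as many on 1 chromosome. The 12 fallen genes on chromosome 1 in the fit of all libraries were Mrpl15, Tcea1, Rrs1, Cspp1, Dst, Satb2, Rasal2, Hspd1, Hspe1, Imp4, Wdr75 and Orc2. Uncalled genes from Mrpl15 to Rasal2 had a median log2 fold change of -0.20.

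**Figure D3:**
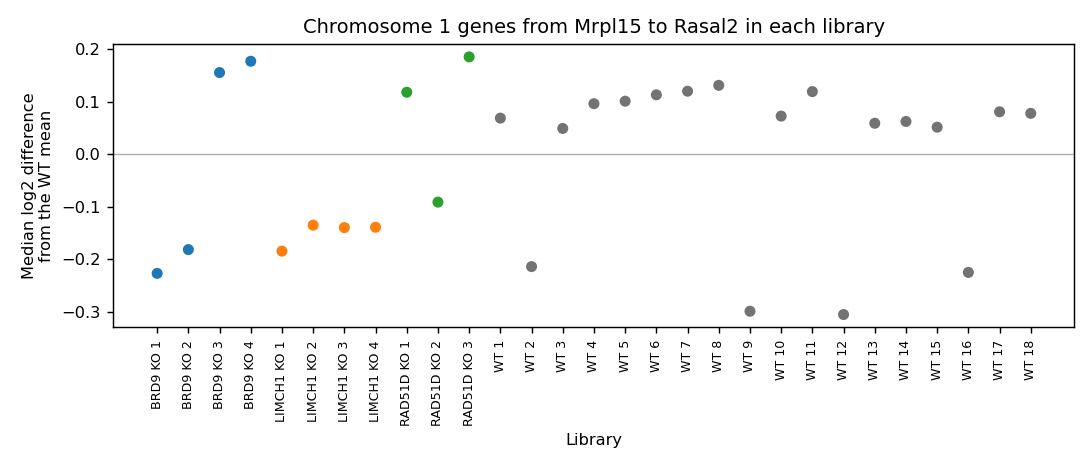
Median log2 difference from the WT mean (vertical axis) over the genes from Mrpl15 to Rasal2 on chromosome 1 in each library, as points, by group. The 4 LIMCH1 knockout libraries lay between -0.18 and -0.13, BRD9 knockout replicates 1 and 2 at -0.23 and -0.18, and WT 9 and WT 12 at -0.30.

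In the interferon lists of LIMCH1 knockout, of 36 interferon-stimulated genes 7 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 fold change of 1.08, 34 positive members and camera adjusted p = 2.44e-18, or adjusted p = 0.0508 with an estimated correlation. Isg15, a ubiquitin-like modifier, was at 3.64 ± 2.22 against 0.721 ± 0.318 CPM and Ifi27 at 32.3 ± 11.5 against 15.1 ± 5.74 CPM. Ifit1 (2.86, SE 0.48) and Ifit3 (1.58, SE 0.35) rose, both uncertain because of close paralogs. Of 16 interferon-gamma GTPases and chemokines 7 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.80 and camera adjusted p = 1.67e-16, or adjusted p = 0.0154 with an estimated correlation. Ccl5, a T-cell chemokine, was at 3.63 ± 2.88 against 0.347 ± 0.385 CPM, and the paralogs Gbp3 (2.27, SE 0.44) and Gbp9 (2.89, SE 0.57) rose from below 1 CPM. Of 21 MHC class I genes 5 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.73 and camera adjusted p = 6.88e-11, or adjusted p = 0.0329 with an estimated correlation. Nlrc5, the transactivator of class I genes, was at 56.3 ± 0.364 against 32.9 ± 9.04 CPM, and H2-K1 (0.82, SE 0.17) and H2-Q4 (1.12, SE 0.27), which share reads with other H2 genes, rose. The libraries differed: 2 of 4 lay above the highest WT library in the interferon-stimulated list (1.19 ± 0.638 mean log2 difference, SD) and in the interferon-gamma list (1.54 ± 0.833). In the class I list 3 of 4 did (0.648 ± 0.188). The 2 above WT in the interferon-stimulated list were replicates 1 and 2, which had like chromosome profiles (r = 0.954). Of 12 cGAS-STING genes 2 rose and 0 fell, Ccl5 and Cxcl10 (2 and 0 adjusted over the list alone; camera adjusted p = 0.0552). Of 20 NF-kB and cytokine genes 2 rose and 0 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0110, and adjusted p = 0.247 with an estimated correlation). They were the neutrophil chemokine Cxcl1 (1.46, SE 0.30) and the inhibitor Nfkbie (0.89, SE 0.21). The members named here had adjusted p from 0.000452 to 0.0476 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

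**Figure D4:**
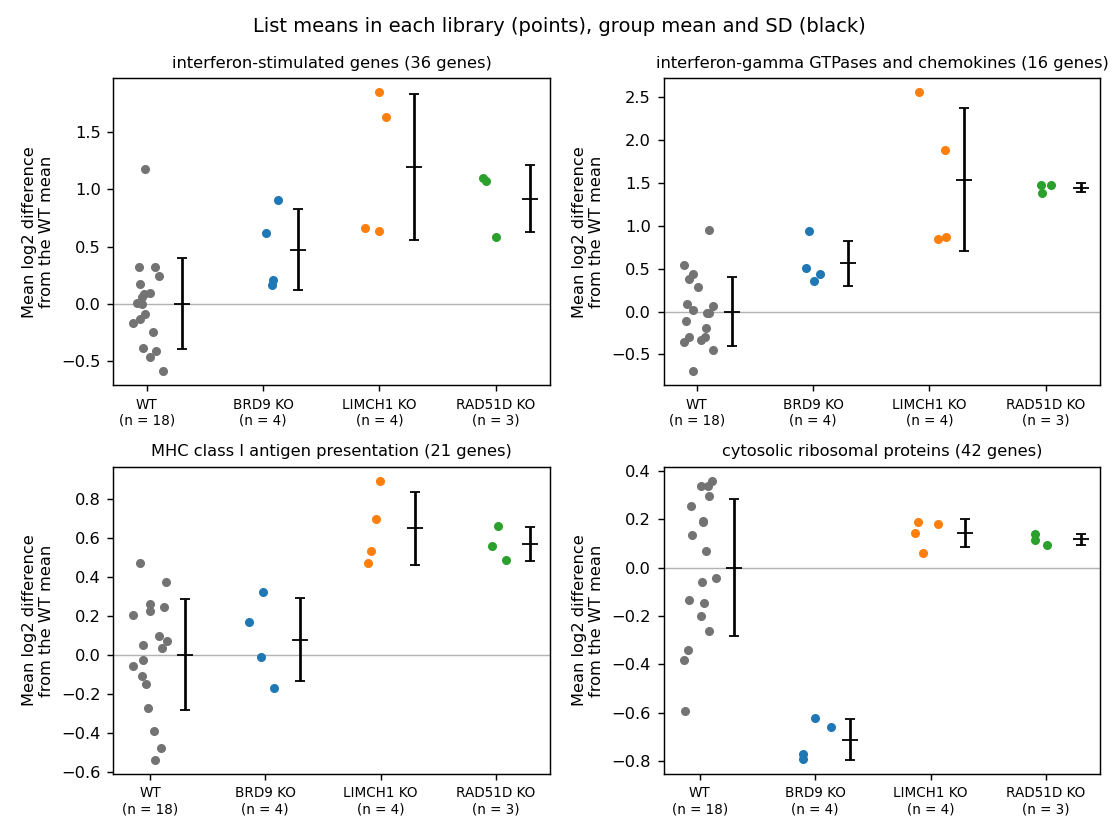
Mean log2 difference from the WT mean (vertical axes) of the members of each of 4 gene lists in each library, as points, by group, with group mean and SD in black. All RAD51D knockout libraries lay above WT in the interferon-gamma and class I lists, LIMCH1 knockout spread widely in the interferon lists, and all BRD9 knockout libraries lay below WT in the ribosomal list.

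In the other lists of LIMCH1 knockout, of 24 cholesterol synthesis genes 0 passed over all genes and 13 were higher adjusted over the list alone (camera adjusted p = 6.88e-11, and adjusted p = 0.133 with an estimated correlation). Msmo1 was at 0.70 (SE 0.18) and Fdft1 at 0.79 (SE 0.21). Of 16 heat shock genes 2 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00285, and adjusted p = 0.247 with an estimated correlation). They were the mitochondrial chaperone pair Hspd1 (924 ± 114 against 1448 ± 240 CPM) and Hspe1 (-0.71, SE 0.16). Both are among the fallen genes on chromosome 1. Neither passed with the neighbour offset (-0.28 and -0.34, edgeR adjusted p = 0.152 and 0.122). Of 28 BAF genes 0 passed over all genes and 4 were lower adjusted over the list alone (camera adjusted p = 7.80e-05, and adjusted p = 0.121 with an estimated correlation), with Phf10 at -0.72 (SE 0.20). Of 21 PD-L1 regulators 1 fell, Fosl1, and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0154, and adjusted p = 0.278 with an estimated correlation). Of 31 mesenchymal genes 0 passed over all genes, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.278 with an estimated correlation), with Col5a1 at 0.81 (SE 0.21). Of 11 fibroblast and endothelial markers 1 rose, Dpt (3.32, SE 0.77), and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.00930, and adjusted p = 0.0508 with an estimated correlation). The remaining lists had 0 calls over all genes by edgeR's quasi-likelihood test and camera adjusted p from 0.0552 to 0.816. Adjusted over the list alone, 2 JAK-STAT-IRF1, 1 checkpoint, 2 actomyosin and 3 leukocyte genes were higher, 1 hypoxia gene was lower, and 0 passed in homologous recombination, p53, YAP and SRF, cell cycle, epithelial, integrated stress, mitochondrial and ribosomal lists. The p53 list had a median of -0.01 with a higher direction in camera, and the actomyosin list a mean of 0.07 with a lower one.

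The number of LIMCH1 calls, Cxcl10 and Tapbp among them, went from 89 to 3 without LIMCH1 knockout replicate 1, 0 without replicate 2 and 20 without replicate 4, and to 178 without WT 2. It was 351 by DESeq2's Wald test, 144 without WT 8, 13 and 14, 20 with the compared groups alone, 52 with the mitochondrial share and 87 without LIMCH1 3 and 4 and RAD51D 2, which have like chromosome profiles. By edgeR's test it was 0 with a surrogate variable or with libraries of like chromosome profile summed, beside 3048 at an unadjusted p under 0.05 with all libraries. Cxcl10 in LIMCH1 KO against WT was at 1.62 (edgeR adjusted p = 0.0564) without replicate 2. Camera's calls of the heat shock and PD-L1 regulator lists ended with a surrogate variable (adjusted p = 0.125 and 0.165), and that of the mesenchymal list with summed libraries (0.0796) or without the 3 like libraries (0.0519).

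RAD51D knockout against WT asks how loss of a recombination factor alters the transcriptome and its immune genes. Apart from Rad51d, 7 genes passed, all of them higher. Stk40, a pseudokinase, was at 56.3 ± 3.48 CPM (n = 3) against 35.0 ± 5.55 CPM in WT (n = 18; log2 fold change 0.69, SE 0.13). The other 6 fell outside the naming rule and were named after their values were seen. They were low transcripts: the DNA sensor Aim2 at 2.87 ± 3.47 against 0.157 ± 0.228 CPM (4.16, SE 0.82) and the interferon-inducible Phf11b at 1.59 ± 0.403 against 0.209 ± 0.183 CPM (2.88, SE 0.51). The remaining ones were Slfn2 (3.09, SE 0.58), the TNF-family ligand Tnfsf18 (3.82, SE 0.69), Atp1a3 (3.04, SE 0.50) and Lipn (3.75, SE 0.74). The 8 genes had adjusted p from 0.0162 to 0.0383 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 moved at least 2-fold, and 1837 genes had an unadjusted p under 0.05. Of the 22 genes called by DESeq2's Wald test 59.1% were higher, against 87.5% here.

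In the lists of RAD51D knockout, of 16 interferon-gamma GTPases and chemokines 0 passed over all genes by edgeR's quasi-likelihood test and 12 were higher adjusted over the list alone, with camera adjusted p = 3.56e-15, and adjusted p = 0.0154 with an estimated correlation. All 3 libraries lay above the highest WT library (1.44 ± 0.0525 mean log2 difference, SD), and Cxcl10, at 8.98 ± 4.06 CPM, had a log2 fold change of 1.57 (SE 0.32, edgeR adjusted p = 0.0573). Of 36 interferon-stimulated genes 0 passed over all genes and 10 were higher adjusted over the list alone (camera adjusted p = 2.98e-11, and adjusted p = 0.121 with an estimated correlation), with Isg15 at 1.48 (SE 0.38), and 0 of 3 libraries lay above the highest WT library (0.918 ± 0.292 mean log2 difference, SD). Of 21 MHC class I genes 0 passed over all genes and 8 were higher adjusted over the list alone (camera adjusted p = 4.07e-08, and adjusted p = 0.0508 with an estimated correlation). Nlrc5 was at 54.5 ± 9.29 CPM and the immunoproteasome subunit Psmb8 at 20.6 ± 3.21 against 7.70 ± 4.56 CPM, and all 3 libraries lay above WT. Of 20 NF-kB and cytokine genes 0 passed over all genes and 8 were higher adjusted over the list alone (camera adjusted p = 6.70e-07, and adjusted p = 0.05002 with an estimated correlation), with Cxcl1 at 1.20 (SE 0.33). Of 34 p53 targets 0 passed over all genes and 1 was higher adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.0641 with an estimated correlation). Gadd45a was at 34.0 ± 1.28 against 10.8 ± 7.10 CPM and the cyclin-dependent kinase inhibitor Cdkn1a at 109 ± 16.9 against 46.2 ± 32.2 CPM. Of 31 homologous recombination genes 1 fell, Rad51d itself, and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.00454, and adjusted p = 0.184 with an estimated correlation), with Rad54b at -0.72 (SE 0.17). Of 12 cGAS-STING genes 1 rose, Aim2, and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.0368, and adjusted p = 0.142 with an estimated correlation). Of 12 checkpoint ligands 0 passed over all genes and 2 were higher adjusted over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.184 with an estimated correlation). Lgals9 was at 0.99 (SE 0.27) and Pvr at 0.83 (SE 0.23).

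The remaining lists of RAD51D knockout held 0 genes called over all genes by edgeR's quasi-likelihood test. Camera placed integrated stress (1 higher of 30 adjusted over the list alone; adjusted p = 2.85e-08, and adjusted p = 0.153 with an estimated correlation) and YAP and SRF targets (1 higher of 22 adjusted over the list alone; adjusted p = 0.000429, and adjusted p = 0.0789 with an estimated correlation) higher. The cystine transporter Slc7a11 was at 42.3 ± 13.5 against 11.0 ± 10.4 CPM and Junb at 0.97 (SE 0.26). It placed cholesterol synthesis (adjusted p = 3.69e-06, and adjusted p = 0.247 with an estimated correlation) and heat shock (adjusted p = 0.000113, and adjusted p = 0.153 with an estimated correlation) lower. It did so also for BAF complexes (adjusted p = 0.00285, and adjusted p = 0.206 with an estimated correlation) and hypoxia and glycolysis (adjusted p = 0.0179, and adjusted p = 0.462 with an estimated correlation), all 4 lists with 0 genes adjusted over the list alone. Hmgcs1 was at -1.16 (SE 0.35), Hspa8 at -0.51 (SE 0.18) and Egln3 at -1.33 (SE 0.48). JAK-STAT-IRF1 genes and PD-L1 regulators, with 1 higher and 1 lower adjusted over the list alone, and the actomyosin, cell cycle, epithelial, mesenchymal, mitochondrial, ribosomal, leukocyte and fibroblast lists, with 0 each, had camera adjusted p from 0.0552 to 0.758. The fibroblast list had a median of -0.13 and a mean of 0.11. The count of 8 changed to 0 without RAD51D knockout replicate 1 or 2, 1 without replicate 3, 27 without WT 2, 3 without WT 4 or WT 6, 4 without WT 5, WT 7 or WT 10 and 5 without WT 11. It was 22 by DESeq2, 3 with the strict filter, 5 with the neighbour offset, 4 with the mitochondrial share, and 0 with a surrogate variable, summed libraries, the compared groups alone or without the 3 like libraries. Camera's call of the checkpoint list ended with summed libraries (adjusted p = 0.0557) or the offset (0.0555), that of cGAS-STING with the offset (0.107), and that of BAF complexes with a surrogate variable (0.154).

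Comparing the knockouts with each other asks which responses belong to one target. BRD9 knockout held more Psd3, an exchange factor for ARF6, than LIMCH1 knockout (27.7 ± 5.25 against 2.65 ± 1.66 CPM, n = 4 each; log2 difference 3.38, SE 0.53) and than RAD51D knockout (3.90, SE 0.62). It held less S100a4 than LIMCH1 knockout (7.71 ± 1.75 against 135 ± 30.2 CPM; -4.13, SE 0.56) and less Klk10 than RAD51D knockout (3.69 ± 1.16 against 57.2 ± 9.36 CPM; -3.95, SE 0.69). Against LIMCH1 knockout the rule also took Prelid2 (4.69, SE 0.92), Fhod3 (3.13, SE 0.63), Sdc3 (3.07, SE 0.96) and 9930111J21Rik2 (3.04, SE 0.66) as higher. It took Phlda2 (-4.28, SE 1.13), Crlf1 (-3.75, SE 0.87), the laminin chain Lamb3 (-3.66, SE 1.02) and Rab15 (-3.60, SE 0.89) as lower. Against RAD51D knockout it took the growth factor Fgf7 (5.43, SE 1.59), Prelid2 (4.98, SE 1.06), Pknox2 (4.20, SE 1.07) and 9930111J21Rik2 (3.54, SE 0.76) as higher. The lower ones were Atp9a (-5.86, SE 1.72), Lamb3 (-4.29, SE 1.07), Phlda2 (-4.12, SE 1.16) and Crlf1 (-4.08, SE 0.90). 9930111J21Rik2, a clone name that does not end in Rik and so passed the rule, has a close copy in the genome, so its value is uncertain. These differences had adjusted p from 6.07e-05 to 0.0164 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Irf1 was lower in BRD9 than in LIMCH1 knockout (-0.58, SE 0.21, edgeR adjusted p = 0.0375), and Stat1 lower in BRD9 than in RAD51D knockout (-0.96, SE 0.35, edgeR adjusted p = 0.0405). Irf1 in BRD9 KO against LIMCH1 KO no longer passed without BRD9 replicate 1 or 2 (edgeR adjusted p = 0.0852 and 0.108) or LIMCH1 replicate 1 or 2 (0.0865 and 0.160). It was also lost with summed libraries (0.297), the mitochondrial share (0.144), a surrogate variable (0.0522), the neighbour offset (0.0599), the replicate block (0.0749) or no filter (0.0712). Stat1 in BRD9 KO against RAD51D KO no longer passed without BRD9 replicate 1 or 2 (0.124 and 0.121) or RAD51D replicate 1 or 3 (0.0976 and 0.215). It was also lost with summed libraries (0.128), the mitochondrial share (0.306), a surrogate variable (0.268), the compared groups alone (0.145) or no filter (0.0805). Fgf7 in BRD9 KO against RAD51D KO no longer passed without RAD51D replicate 3 (0.0602). Cd274 did not differ past the test in any pair (edgeR adjusted p = 0.396, 0.961 and 1). In all 2509 genes were higher and 2765 lower in BRD9 than in LIMCH1 knockout, and 2076 higher and 2610 lower than in RAD51D knockout. Between LIMCH1 and RAD51D knockout edgeR's quasi-likelihood test called 0 genes and DESeq2 14. By edgeR's test 723 of 16240 genes had an unadjusted p under 0.05, a share below 0.05. The first count, 5274, dropped to 8 with summed libraries, 373 with the mitochondrial share and 1106 with a surrogate variable. Of the 10 genes the rule took against LIMCH1 knockout only S100a4 still passed with summed libraries, and S100a4, Psd3 and Sdc3 with the mitochondrial share. Of the 10 against RAD51D knockout Atp9a, Lamb3 and Phlda2 were lost with summed libraries, and all but Psd3 and Klk10 with the mitochondrial share. The second, 4686, dropped to 1544, 308 and 1518 in the same settings and to 3087 and 3066 without RAD51D knockout replicate 1 or 3, while the third was 153 in a fit of the compared groups alone. Without LIMCH1 3 and 4 and RAD51D 2 the counts were 3123, 2773 and 0.

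Because every knockout was set against the same WT libraries, fold changes of the knockouts share chance values. Across 16240 genes, which are not independent replicates, the log2 fold changes of LIMCH1 and RAD51D knockout correlated at Pearson's r = 0.65 with a covariance of 0.166, against 0.159 and 0.0201 on average in 100 simulated pairs of unchanged groups. The values were 0.536 and 0.145 with separate WT libraries for each knockout. The surrogate variable was 0.0899 to 0.189 in WT 1 to 7. It was -0.397 to -0.0770 in WT 8 and WT 12 to 18, and -0.0596 to 0.0339 in WT 9 to 11. All LIMCH1 and RAD51D knockout libraries lay at 0.143 to 0.236, on the side of WT 1 to 7. Random splits mix these WT libraries, so they cannot remove an offset from the WT mean that both knockouts share. The correlation therefore does not separate shared knockout effects from such an offset. LIMCH1 3 and 4 shared a chromosome profile with RAD51D 2 (r = 0.883 and 0.872). Without these 3 libraries, which left 2 per group, r was 0.51 and the covariance 0.169, against simulated 0.0987 and 0.0200. BRD9 knockout correlated at -0.10 with LIMCH1 and at -0.18 with RAD51D knockout (covariance -0.0343 and -0.0601, against simulated 0.0201 and 0.0202, and -0.0548 and -0.0806 with separate WT libraries). The surrogate variable was 0.0565 and 0.000404 in BRD9 knockout 1 and 2, and -0.279 and -0.315 in 3 and 4. These negative correlations likewise do not separate knockout effects from offsets from the WT mean. Phf11b rose in both LIMCH1 (2.23) and RAD51D knockout (2.88), the only gene called in both, and 0 fell in both. Independent lists would share 0.0280 rises, and the top genes of simulated unchanged groups with the same WT libraries shared 0.500 on average. BRD9 shared 9 rises and 4 falls with LIMCH1 knockout (8.64 and 3.92 for independent lists, 21.6 and 8.33 simulated). It shared 2 rises and 0 falls with RAD51D knockout (0.931 and 0.163, and 2.79 and 0.420). The first value leaves out the shared WT libraries and the second the effects, so neither is a value without shared changes.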

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

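The tests with libraries of like chromosome profile summed, with whole lines split, with the neighbour offset and with the mitochondrial share were chosen after the results were seen; the tests between knockouts and the counts over other splits of the samples were not. Irf1, a transcription factor of the interferon response, was 0.58 lower on the log2 scale in BRD9 than in LIMCH1 knockout (-0.58, SE 0.21, edgeR adjusted p = 0.0375), a difference between effects that were -0.07 and 0.51 against WT. Stat1 was lower in BRD9 than in RAD51D knockout by a log2 difference of -0.96 (SE 0.35, edgeR adjusted p = 0.0405), with effects of -0.35 and 0.60 against WT. Each drew attention because the knockouts' effects differed in a direct test by edgeR's quasi-likelihood model, while neither gene passed against WT in any of these knockouts. Irf1 in BRD9 KO against LIMCH1 KO no longer passed without BRD9 replicate 1 or 2 or LIMCH1 replicate 1 or 2 (edgeR adjusted p = 0.0852, 0.108, 0.0865 and 0.160), with libraries of 1 line summed (0.297) or with the mitochondrial share (0.144). It was lost as well with a surrogate variable (0.0522), the neighbour offset (0.0599), the replicate block (0.0749) or no filter (0.0712). Stat1 in BRD9 KO against RAD51D KO no longer passed without BRD9 replicate 1 or 2 or RAD51D replicate 1 or 3 (0.124, 0.121, 0.0976 and 0.215), with lines summed (0.128) or with the mitochondrial share (0.306). It was lost as well with a surrogate variable (0.268), the compared groups alone (0.145) or no filter (0.0805). The effect of BRD9 knockout differed from that of LIMCH1 knockout in 5274 genes and from that of RAD51D knockout in 4686, S100a4, Klk10, Psd3 and Prelid2 among them.

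BRD9 knockout changed 4813 genes, among them Dpt, Sema3c, S100a4 and 37 of 42 cytosolic ribosomal protein genes (36 lower and 1 higher), a list that camera called with adjusted p = 1.21e-14 but not with an estimated correlation (adjusted p = 0.142). Among 100 splits of single libraries only the real one called as many genes (4813, highest other 1475). Against LIMCH1 knockout the real count was likewise the highest (1 of 35 splits, 5274, highest other 159). So it was against RAD51D knockout (1 of 35 splits, 4686, highest other 1968). Such splits take libraries as exchangeable, which those of 1 line are not, so they do not exclude chance by themselves. Of 136 splits of whole lines 3, the real one included, called at least 746 genes (a share of 0.0221). The other 2 joined a BRD9 line to WT 8, at up to 2804, which points to a structure of the samples, and the highest of the 105 splits with WT lines alone was 487. With lines summed the counts against LIMCH1 and RAD51D knockout were 8 and 1544, and lines were too few there for a share of splits under 0.05. Shifts shared by neighbouring genes are not enough for the count, because an offset for neighbouring genes left 5008 genes called. The offset cannot remove effects of chromosome-scale differences on genes elsewhere, so such differences between lines stay open. The 4 libraries form 2 pairs with near-identical profiles along the chromosomes (r = 0.927 and 0.964). Summing libraries of 1 line lowered the count to 746. With only 2 BRD9 libraries against WT, also counted after the results were seen, the 2 pairs of 1 line called 2750 and 3011 genes. The 4 pairs across lines called 747 to 2465. Much of the count may therefore rest on lines counted as independent samples. A difference in RNA quality, read as the mitochondrial share, could account for part as well, with 1610 genes called beside that covariate. It cannot be told apart from loss of BRD9, which stays open, because all 4 BRD9 libraries held 3.44% or more, against a WT mean of 2.77%. Only WT 8, 14 and 18, at 11.0, 3.90 and 4.03%, lay above 3.44%, so the shares overlap in few libraries.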

How the results depend on the processing

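Summed lines, neighbour offset, mitochondrial share, omission of WT 8, 13 and 14 and omission of 3 like libraries (LIMCH1 3 and 4, RAD51D 2) were tests chosen after seeing the data. Dpt, Sema3c, S100a4 and Brd9 kept their direction in BRD9 knockout under every alternative. The 4813 genes became 1320 with a 2-fold minimum, 746 with lines summed and 1610 with the mitochondrial share. The 89 LIMCH1 genes became 58 with a 2-fold minimum, 351 by DESeq2, 0 with a surrogate variable, 20 in a fit of the compared groups alone, 0 with lines summed, 52 with the mitochondrial share and 144 without 3 WT libraries. Leaving out 1 library gave 0 to 178. The 8 RAD51D genes became 22 by DESeq2, 3 with the strict filter, 0 with a surrogate variable, with the compared groups alone, with lines summed or without 3 like libraries, 5 with the neighbour offset and 4 with the mitochondrial share. Leaving out 1 library gave 0 to 27. The 5274 genes of BRD9 against LIMCH1 knockout became 2437 with a 2-fold minimum, 1106 with a surrogate variable, 8 with lines summed, 373 with the mitochondrial share and 3123 without 3 like libraries. The 4686 against RAD51D knockout became 2327, 1518, 1544, 308 and 2773 in these settings, with 3066 to 4470 when 1 library was left out. The 0 genes of LIMCH1 against RAD51D knockout became 14 by DESeq2, 1 with DESeq2 size factors, the strict filter or the mitochondrial share, and 153 with the compared groups alone. A 2-fold minimum asks for more by construction, and fewer samples follow from summing; for the other changes the cause was not tested.

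With the replicate number as a block the calls were 5381, 295 and 0 against WT for BRD9, LIMCH1 and RAD51D knockout, 5109 for BRD9 against LIMCH1 and 5155 for BRD9 against RAD51D knockout. The numbers do not pair the libraries: 3 of 21 pairs correlated above 0.1 (-0.231 to 0.138), and in 8 of 21 a library matched its own number best. Under this block camera no longer called, in BRD9 knockout, the interferon-gamma (0.558), cGAS-STING (0.104), mesenchymal (0.0598) and cholesterol lists (0.376). In LIMCH1 knockout it no longer called PD-L1 regulators (0.339), BAF (0.0598) and heat shock (0.894, now higher), and in RAD51D knockout BAF (0.242), homologous recombination (0.370), p53 (0.0776), hypoxia (0.558), integrated stress (0.485, now lower), cholesterol (0.513) and heat shock (0.376).

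Rad51d in RAD51D KO against WT had log2 fold changes of -0.84 to -0.62 when 1 library was left out, and Brd9 in BRD9 KO against WT -1.16 to -0.65. Cd274 in LIMCH1 KO against WT, near 0 at -0.01, changed sign with total counts (0.11), a surrogate variable (0.16), the block (0.17), lines summed (0.042), the neighbour offset (0.19), the mitochondrial share (0.038), without 3 WT libraries (0.037) and without 3 like libraries (0.21). It ranged from -0.18 to 0.094 when 1 library was left out. Stat1 in LIMCH1 KO against WT changed sign with total counts (0.11), the strict filter (0.00020), the offset (0.36) and without 3 like libraries (0.14), and ranged from -0.14 to 0.088 when 1 library was left out. Jak1 in LIMCH1 KO against WT was 0.082 with a surrogate variable and 0.069 with the block, Jak1 in RAD51D KO against WT 0.050 and 0.12, and Jak1 in BRD9 KO against WT -0.061 with the mitochondrial share. Irf1 in RAD51D KO against WT was 0.013 with a surrogate variable and 0.53 with the block, and Irf1 in BRD9 KO against WT 0.44 with the block and -0.14 to 0.0056 when 1 library was left out. None of these values had passed the test, and the cause was not tested.

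With an estimated correlation 0, 2 and 1 lists were called for BRD9, LIMCH1 and RAD51D knockout instead of 9, 10 and 14; this setting allows for members that vary together. The covariances of shared fold changes with WT libraries split were -0.0548, -0.0806 and 0.145. The last pair, LIMCH1 and RAD51D knockout, had 0.169 without 3 like libraries, against 0.166. Total counts moved the median of all genes by 0.11 in LIMCH1 knockout, from -0.00024 to 0.11, and by -0.14 in BRD9 against LIMCH1 knockout, from -0.053 to -0.20. The share of higher genes among those called went from 73.0 to 86.5% in LIMCH1 knockout and from 47.6 to 35.4% in BRD9 against LIMCH1 knockout. By DESeq2's Wald test it was 41.9% in LIMCH1 knockout and 59.1%, against 87.5%, in RAD51D knockout. Of the 33 called lists 0 changed the sign of their median under the scalings. For named genes, 2238 of the values under alternatives other than leaving out 1 library kept direction and side of the threshold, 384 became weaker, 18 stronger and 12 changed sign. When 1 library was left out the counts were 3527, 312, 8 and 10. Of those that became weaker outside leave-one-out, 107 came with lines summed, 76 with the mitochondrial share, 56 with a surrogate variable, 39 with the compared groups alone, 32 without 3 like libraries and 29 with the block. Depth limits Limch1, with 23 counts over 18 WT libraries.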

Other observations

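The tests of a line shared with RAD51D knockout, of the loss of Limch1 mRNA, of the neighbour offset and all tests on chromosome 1 were chosen after the results were seen. Some transcripts abundant elsewhere were nearly absent in 1 or a few libraries. Malat1, a nuclear long noncoding RNA with a median of 309.6 CPM, had 0 counts in WT 13, and Neat1, the scaffold RNA of paraspeckles with a median of 592 CPM, had 0 in WT 14. Rps6ka6, a ribosomal S6 kinase (median 26.1 CPM), had at most 1 count in WT 12, 13, 14, 16, 17 and 18, and Lrch2 (20.2 CPM) 0 in WT 17 and 18. Loxl2 (17.6 CPM) and Tmem47 (22.4 CPM) had 0 in WT 12, and Khdrbs3 (12.1 CPM) 0 in BRD9 knockout 1 and 2 and RAD51D knockout 1. In all 17 genes with a median of at least 10 CPM had 3 counts or fewer in some library, 9 of them in 1 library alone. Whether such WT libraries carry edits of their own was not tested and stays open, and it bears on what WT means in every contrast. Without WT 8, 13 and 14 the calls against WT were 6250 for BRD9, 144 for LIMCH1 and 11 for RAD51D knockout, instead of 4813, 89 and 8.

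Profiles of expression along the chromosomes, in 171 windows of 50 genes, paired some libraries. BRD9 knockout 1 and 2 correlated at Pearson's r = 0.927, BRD9 knockout 3 and 4 at 0.964, LIMCH1 knockout 1 and 2 at 0.954 and LIMCH1 knockout 3 and 4 at 0.935. Among WT libraries, WT 4 and 5 correlated at 0.951, WT 6 and 7 at 0.951 and WT 17 and 18 at 0.822, against a median of -0.056 over the 406 pairs. LIMCH1 knockout 3 and 4 also matched RAD51D knockout 2, at 0.883 and 0.872. These are correlations across windows within pairs of libraries, and windows are not independent replicates.

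In LIMCH1 knockout 7 of 36 interferon-stimulated and 5 of 21 MHC class I genes passed as higher, Isg15, Nlrc5 and Tapbp among them. Camera called both lists (adjusted p = 2.44e-18 and 6.88e-11), but with an estimated correlation only the class I list (0.0329, against 0.0508). A line shared with RAD51D knockout 2 is not enough, because LIMCH1 knockout 1 and 2, which lack that profile, lay above every WT library. This held in the interferon-stimulated list, where LIMCH1 knockout 3 and 4 lay within the WT range. In that list only 1 line, LIMCH1 knockout 1 and 2, therefore lay above the WT range. All 4 LIMCH1 libraries lay at least 0.632 above the WT mean, where the WT libraries had an SD of 0.397. Shifts shared by neighbouring genes are not enough for the class I list. It kept an adjusted p of 1.35e-10 by camera with the neighbour offset, at the preset correlation. The offset cannot remove effects of chromosome-scale differences on genes elsewhere, so such differences between lines stay open for both lists. Loss of Limch1 mRNA is an unlikely route, since the pooled WT level had an upper 95% limit of 0.0477 CPM, or 0.0580 CPM with 2 counts taken as 1 fragment. WT 14, the highest library, held 0.238 CPM. An edit acting otherwise or away from its target was not tested. Of 100 splits of the libraries 4, the real one included, called at least 89 genes, a share of 0.04. The other 3, of WT libraries alone and each with WT 8, called 1477, 1450 and 790, which points to a structure of the samples. Such splits take libraries as exchangeable, which those of 1 line are not, so this share does not exclude chance. By their chromosome profiles the 4 LIMCH1 libraries were taken as 2 lines. With lines summed edgeR called 0 genes, so chance differences between whole lines stay open. For RAD51D knockout, where Phf11b and Stk40 rose, 15 of 100 splits called at least the real 8 genes and chance could not be excluded (highest other 2064, WT 8, 14 and 17, again a structure of the samples). Between LIMCH1 and RAD51D knockout edgeR called 0 genes and DESeq2 14. By edgeR's test 723 of 16240 genes had an unadjusted p under 0.05, less than the share of 0.05 that unchanged genes would give on average. In 35 of 35 splits at least 0 genes were called, with a highest other of 1. A real count of 0 therefore leaves this comparison without information on chance.

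Of the 23 placed genes that fell in LIMCH1 knockout 12 lay on chromosome 1, among them Mrpl15, Hspd1, Hspe1 and Dst. Fisher's exact p was 1.40e-09 (odds ratio 17.4), but it ignores that the chromosome was chosen from these genes and that neighbours shift together, so it excludes nothing. With lines summed, 6 of the 23 most fallen genes lay on chromosome 1, and 41 of 106 groupings of lines, the real one included, placed as many on 1 chromosome, with up to 18 for 2 WT lines. Chance placement could therefore not be excluded. From Mrpl15 to Rasal2, 607 uncalled genes had a median log2 fold change of -0.20, with 426 below 0. The other placed genes of chromosome 1 had a median of -0.10. Of 1000 random stretches of like length 0 lay as low (lowest -0.197). These could overlap each other and the tested stretch and cross chromosome ends, and fallen genes of the same data set its ends. Their count therefore gives no measure of chance. A lower dosage of this stretch may contribute, but it cannot be told apart from other causes. WT 2, 9, 12 and 16 lay at -0.21, -0.30, -0.30 and -0.22 as well, and BRD9 knockout 1 and 2 at -0.23 and -0.18. With the neighbour offset the 12 genes went from a median of -0.79 ± 0.166 to -0.42 ± 0.169 (SD), and only Rasal2 still passed (edgeR adjusted p = 0.0169), so the change beyond their neighbours stays open.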
